A study of Mus musculus with 6 samples.

How the data were processed

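Whole brains of 3 infected and 3 control mice were measured, 1 array per mouse, so replicates were separate animals. Per the labels' protocols, total brain RNA was labelled with Cy3 and the composite reference with Cy5, in the same orientation on all 6 arrays, with no dye swap. The deposited table gave 1 log2 value per spot and array, with 31.0% to 45.5% of spots empty. How the authors corrected background, filtered spots and normalized is not given in the sources used here, nor is what an empty value means. Scale and direction were settled from the values: between 77.4% and 91.5% of values on an array equalled log2 of a fraction of whole numbers with a denominator of at most 1000, within 1e-09, against at most 0.131% after the values were shifted at random. For the values matched, a ratio of whole numbers leaves little room for a scaling of the ratios specific to an array. Subtraction of a whole-number background or filtering of spots would leave such ratios, so neither is excluded. The medians of the deposited columns were 0.25, 0.00 and -0.31 for control replicates 1 to 3, and 0.33, 0.23 and -0.21 for infected replicates 1 to 3. The direction, brain over reference, came from genes enriched in brain or in other tissues.

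The layout of 48 blocks of 700 spots was inferred from the order of the spots, and empty spots repeated with a period of 28 spots on all 6 arrays. Block medians spanned 0.46 to 1.92 log2 units within an array, so the values were normalized. Each block was centred on its median, the arrays were scaled to a common median absolute deviation, and each array was centred on the median of the spots measured on all 6. The plan made before the data were examined had been to use the values as deposited. Block centring and scaling were chosen from the spread within groups, before any test of infected against control. The final centring was added after a first fit, which also gave 0 features past the threshold, with 661 features higher and 1294 lower at an unadjusted p under 0.05, against 1024 and 830 with it.

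Of 33600 spots, 18179 had 1 gene symbol, 87 several and 15334 none in the platform annotation, which gave 13658 genes. Through Entrez IDs and a gene table of GRCm38.p6, used for names only, 6 symbols were updated and 9 IDs were not found and kept their symbol. Spots with several symbols or none were tested unnamed. No coordinates are given because the build of the array design is not given in the sources used here. A spot needed at least 2 values in each group. The 2663 genes with more than 1 spot took an additive fit of spot and array over their spots, which equals the mean where no value is missing.

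Infected and control brains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05 over 16470 features). Gene lists were fixed before the data were examined, 39 for the comparison and 2 for the direction of the ratio, and 33 of the 39 had at least 5 measured genes. They were tested with the camera statistic at a preset correlation of 0.01 between genes, computed on the moderated statistics because many spots are empty, with Benjamini-Hochberg adjustment over the 33. The lists were also tested with an estimated correlation and with fry, as planned. Named genes were set by rule: with fewer than 10 past the threshold, the 10 in each direction with the smallest unadjusted p, placeholder symbols left out, and up to 4 members per list by the same measure. Standard errors are those of limma. Tables were read with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots were drawn with matplotlib 3.10.9.

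The procedure was tested on simulated data with the real layout, empty spots and spread. Of 50 genes changed at each size, the test called 12% at a log2 change of 1, 38% at 1.5, 72% at 2 and 90% at 3, and it called 1 unchanged gene among 16470 features. A list moved by 0.7 was called in 19 of 20 draws, and 5 of 640 tests of unmoved lists were called. Genes in that simulation varied independently, so it does not cover genes that vary together.

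The alternatives were 16 planned settings and 7 added after the data were seen, besides the estimated correlation and fry for lists and 2 other thresholds. The planned ones covered normalization, the spots and genes used, the variance model, array weights, the replicate number as a block, a filter on low ratios and each array left out. The added ones were block medians without scaling, print-tip loess on intensities recovered from the fractions, block medians followed by quantile normalization, no final centring, a plain mean over spots, named genes only, and spots without dim signal. Recovered intensities are in lowest terms and so are lower bounds. Medians in the reference channel were 391, 474 and 523 on control replicates 1 to 3. On infected replicates 1 to 3 they were 237, 331 and 263. Medians in the brain channel were 506, 465 and 401 against 292.5, 383 and 237. Values matched as fractions were 77.4% to 78.7% on control and 83.9% to 91.5% on infected arrays. With a reference common to all arrays, a difference between arrays runs alongside infection and cannot be separated from it. Scanner intensities as such and slide or scan dates were not analysed here.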

Results

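Brain RNA was profiled from female C57Bl/6 mice infected with *Plasmodium berghei* ANKA, a rodent malaria parasite used as a model of cerebral malaria, and from mice that received uninfected blood. Each group held 3 mice, and brains were taken on day 6 after infection. Each brain was hybridised on its own 2-colour array of mouse oligonucleotides, with the brain RNA in Cy3 and a composite reference from several adult tissues in Cy5. The arrays held 33600 spots, of which 18307 to 23181 carried a value on a given array. The measured quantity was the log2 ratio of brain over reference, and its precision was limited by the number of arrays. The comparison addressed which transcripts differ between the infected and the control brain.

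Genes enriched in brain set the direction of the ratio. Their median log2 ratio was 1.46 to 2.62 on the 6 arrays, and that of genes enriched in liver, kidney, heart, lung, stomach, spleen or gonad was -5.89 to -3.44. A positive value therefore meant more signal in brain than in the reference on 6 of 6 arrays.

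Between infected and control brains, the genes with the smallest p on the higher side included *Cpxm1*, *Cyp2c40*, *Mep1a*, *Tmprss2*, *Gimap6*, *Arhgef5*, *Myl7*, *Dnaja4*, *Ccl24* and *Slc7a7*, and none of them passed the threshold. *Gimap6*, a GTPase of lymphocytes (Entrez 231931), had a log2 ratio of -1.38 ± 0.44 (SD, n = 3) in control and 0.48 ± 0.57 (SD, n = 3) in infected brains. *Ccl24*, a chemokine (Entrez 56221), had 0.07 ± 0.57 (SD, n = 3) and 1.69 ± 0.20 (SD, n = 3). *Dnaja4*, a co-chaperone of heat shock protein 70, had a log2 change of 1.43 ± 0.27 (SE). On the lower side were *Serpina1d*, *Tff1*, *Htr1a*, *Cpne9*, *Bsn*, *Chrm1*, *Rims2*, *Rlbp1*, *Hivep2* and *Usp33*, likewise short of the threshold. *Bsn* encodes the presynaptic scaffold bassoon and had a log2 change of -1.36 ± 0.31 (SE), *Rims2* encodes a regulator of vesicle release and had -1.39 ± 0.33 (SE), *Chrm1* encodes a muscarinic acetylcholine receptor and had -1.17 ± 0.27 (SE), and *Htr1a* encodes a serotonin receptor and had -1.34 ± 0.29 (SE).

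Of 16470 features tested with limma, comprising 8691 named genes and 7779 unnamed spots, 0 passed a Benjamini-Hochberg adjusted p under 0.05, 0 higher and 0 lower in infected brains. The smallest adjusted p from limma was 0.227. At an unadjusted p under 0.05 limma gave 1854 features, 1024 higher and 830 lower, where 823.5 would be expected with no change. Groups did not overlap in 3548 features, 21.5% of those tested, where chance gives 13.5% at their numbers of values. Among the 11984 features measured on all 6 arrays they did not overlap in 2153, or 18.0%, where chance gives 10%. The share higher depended on scaling: it was 55.2% here, 77.7% in the values as deposited, 29.8% after quantile normalization and 33.8% without the final centring of arrays. Quantile normalization moved the median change of all features to -0.15 and leaving out the centring moved it to -0.10, against -0.0044 here.

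Genes of antigen presentation by MHC class I, which displays peptides to CD8 T cells, were higher on average in infected brains. All 13 measured members were higher, with a median log2 change of 0.87, or 1.83-fold, and camera gave an adjusted p of 0.000287 over 33 lists. With an estimated correlation between genes the adjusted p was 0.607. No member passed over all genes tested (0 of 13), and 1 passed when adjusted over the list alone. *H2-Q10*, a class I heavy chain, had a log2 ratio of -2.20 ± 0.71 (SD, n = 3) in control and -0.81 ± 0.21 (SD, n = 3) in infected brains. The log2 change was 1.21 ± 0.39 (SE) for *Tapbp*, the peptide-loading chaperone tapasin, 1.16 ± 0.47 (SE) for *H2-K1* and 1.11 ± 0.46 (SE) for *B2m*, the light chain of class I molecules. The control brains did not agree among themselves. Relative to the control mean, the list mean was -0.50 and -0.61 in control replicates 1 and 2, 1.12 in control replicate 3, and 0.77, 0.84 and 1.00 in the infected brains. The exact permutation p of the list means was 0.4, two-sided, and 3 against 3 cannot go below 0.1. Over all lists camera called 8, and 4 of the 10 splits of the arrays into 3 and 3, the real one among them, called as many.

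Interferon-stimulated genes were also higher on average, in 10 of 11 members, with a median log2 change of 0.53. Camera gave an adjusted p of 0.00211, and 0.607 with an estimated correlation. *Ifit3*, which restrains viral translation, had a log2 change of 1.69 ± 0.48 (SE), *Trim30a* had 1.02 ± 0.36 (SE) and *Dhx58*, a sensor of viral RNA, had 0.76 ± 0.32 (SE), and 0 of 11 members passed over all genes or adjusted over the list alone. Control replicate 3 lay at 0.63 in the list mean, within the infected range of 0.38 to 0.94, while control replicates 1 and 2 lay at -0.20 and -0.43 (exact permutation p = 0.2). The call was lost without control replicate 1 (camera, adjusted p = 0.0872, median log2 change 0.35). The interferon-gamma-inducible GTPases had 4 measured members, too few for a test. *Tgtp1*, *Gbp2* and *Gbp3* had log2 changes of 1.67 ± 0.75 (SE), 1.68 ± 0.89 (SE) and 1.03 ± 0.64 (SE), and *Gbp5* had -0.01 ± 0.23 (SE). The first 3 had no value in control replicate 2, and their differences rested on control replicate 1, since control replicate 3 had log2 ratios of 1.87, 3.01 and 2.06 against infected means of 1.88, 2.68 and 1.85.

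Genes of reactive astrocytes and genes that respond to glucocorticoids were higher on average, in all 12 and all 14 measured members. Their median log2 changes were 0.50 (camera, adjusted p = 0.00265) and 0.41 (camera, adjusted p = 0.00302), and both had an adjusted p of 0.607 with an estimated correlation. *Lcn2*, the iron-binding protein lipocalin 2, had a log2 change of 1.54 ± 0.59 (SE) and *Serpina3n*, a protease inhibitor of reactive astrocytes, 1.18 ± 0.49 (SE). In the glucocorticoid list *Sult1a1*, a sulfotransferase, had 1.68 ± 0.55 (SE), *Sgk1*, a kinase of ion transport, 1.31 ± 0.48 (SE) and *Cdkn1a*, an inhibitor of the cell cycle, 1.41 ± 0.60 (SE). *Sult1a1* had no value in control replicate 1 and rested mostly on control replicate 2 at -2.42. Control replicate 3 had -0.33, against -0.22 to 0.74 in infected brains. *Cdkn1a* had 1.815 in control replicate 3, above every infected brain at 1.01 to 1.75. *Serpina3n* rested mostly on control replicate 2 at -2.13, since control replicate 3 had 0.29 against 0.30 to 0.47 in infected brains. No member of either list passed over all genes or adjusted over the list alone (0 of 12 and 0 of 14). Control replicate 3 again lay with the infected brains, at 0.59 and 0.82 in the list means, against infected ranges of 0.39 to 0.97 and 0.44 to 0.71 (exact permutation p = 0.2 and 0.4). The glucocorticoid list lost its call without control replicate 1 (camera, adjusted p = 0.113, median log2 change 0.12) or 2 (camera, adjusted p = 0.111, median 0.23). The astrocyte list lost its call without infected replicate 3 (camera, adjusted p = 0.123, median 0.33). It also lost the call without the 25% of features with the lowest log2 ratios (camera, adjusted p = 0.102, median 0.45).

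Genes of cell division were higher on average in infected brains, and here the control brains lay together. All 9 measured members were higher, with a median log2 change of 0.70, or 1.63-fold (camera, adjusted p = 0.00232; adjusted p = 0.607 with an estimated correlation). *Aurka*, a mitotic kinase, had a log2 change of 1.23 ± 0.31 (SE), *Rrm1*, a subunit of ribonucleotide reductase, 1.04 ± 0.36 (SE), *Mcm2*, a part of the replicative helicase, 0.70 ± 0.28 (SE) and *Bub1b*, a checkpoint kinase, 0.52 ± 0.24 (SE). Of the 9 members 0 passed over all genes and 1 passed adjusted over the list alone. The list mean was -0.14 to 0.13 in the control and 0.30 to 0.89 in the infected brains. The 3 infected brains lay above every control, at an exact permutation p of 0.1, the smallest that 3 against 3 can give. Most members had low log2 ratios: without the 25% of features with the lowest ratios 2 of the 9 were left, too few to test the list.

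Genes of endothelial activation were higher on average, in 12 of 13 members, with a median log2 change of 0.22. Camera gave an adjusted p of 0.0136, and 0.607 with an estimated correlation. *Vwf*, the von Willebrand factor that binds platelets, had a log2 change of 1.29 ± 0.40 (SE), *Icam1* and *Icam2*, adhesion molecules for leukocytes, had 1.20 ± 0.46 (SE) and 1.00 ± 0.36 (SE), and *Plat*, the tissue plasminogen activator, had 1.03 ± 0.43 (SE). *Vwf* and *Icam1* had no value in control replicate 2, *Icam2* none in infected replicate 3 and *Plat* none in infected replicate 2. *Icam1* rested mostly on control replicate 1 at -2.155, since control replicate 3 had -0.39 against -0.30 to 0.19 in infected brains. *Plat* had 1.44 in control replicate 3, above infected replicate 1 at 1.21. No member passed over all genes or adjusted over the list alone (0 of 13). The list mean was -0.17, -0.08 and 0.26 in the control and 0.39, 0.62 and 0.31 in the infected brains (exact permutation p = 0.1, the smallest possible). The median of the list lay at percentile 94.6 of 10000 random lists matched on mean log2 ratio. The call was lost over genes measured on all 6 arrays (adjusted p = 0.288), without dim spots (adjusted p = 0.0580) and without the 25% of features with the lowest log2 ratios (adjusted p = 0.0781). It was also lost without control replicate 1 (adjusted p = 0.180), infected replicate 1 (adjusted p = 0.0595) or infected replicate 2 (adjusted p = 0.141). Genes of the blood-brain barrier endothelium did not pass, with 10 of 15 higher (camera, adjusted p = 0.213), though they passed in 3 of 17 settings that kept all arrays and the preset correlation.

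Genes of GABAergic transmission, the inhibitory signalling of the brain, were lower on average in infected brains. Of 12 measured members 11 were lower, with a median log2 change of -0.45 (camera, adjusted p = 0.00700; adjusted p = 0.607 with an estimated correlation). *Gabrb2*, a subunit of the GABA-A receptor, had a log2 ratio of 2.40 ± 0.23 (SD, n = 3) in control and 1.44 ± 0.27 (SD, n = 3) in infected brains. The interneuron peptides *Sst* (somatostatin) and *Npy* (neuropeptide Y) had log2 changes of -0.92 ± 0.29 (SE) and -0.55 ± 0.31 (SE), and the receptor subunit *Gabrd* had -0.90 ± 0.46 (SE). The *Gabrd* difference rested on infected replicate 3 at -0.01. Infected replicates 1 and 2 had 1.83 and 1.90, within the control range of 1.78 to 2.39. For *Npy*, infected replicate 1 at 1.43 lay within the control range of 1.25 to 1.69, and infected replicate 3 had 0.27. Over all genes 0 of 12 passed, and 1 passed adjusted over the list alone. The list means overlapped, at -0.26, 0.01 and 0.25 in the control and -0.19, -0.71 and -0.50 in the infected brains (exact permutation p = 0.2). The call was lost without control replicate 3 (camera, adjusted p = 0.0642, median log2 change -0.27) and without infected replicate 2 (camera, adjusted p = 0.119, median -0.33).

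Genes of oxidative phosphorylation, which makes ATP in mitochondria, were lower by a small amount, with 19 of 24 lower and a median log2 change of -0.13 (camera, adjusted p = 0.0424; adjusted p = 0.607 with an estimated correlation). *Cox7a2*, *Ndufb8* and *Cox5a*, subunits of the respiratory chain, had log2 changes of -0.72 ± 0.26 (SE), -0.59 ± 0.24 (SE) and -0.50 ± 0.23 (SE), and 0 of 24 passed over all genes or adjusted over the list alone. The median of the list lay at percentile 37.0 of 10000 random lists matched on mean log2 ratio, whose own median was -0.10. The list means overlapped, at -0.04, 0.16 and -0.12 in the control and -0.16, -0.36 and -0.07 in the infected brains (exact permutation p = 0.2). The call was lost in 8 of the 17 settings that kept all arrays and the preset correlation, among them the values as deposited (adjusted p = 0.0752), print-tip loess (adjusted p = 0.560) and leaving out the 25% of features with the lowest log2 ratios (adjusted p = 0.900). The median log2 change in these settings was -0.24, -0.05 and -0.06, in that order. It was -0.26 after median centring and -0.02 with block medians unscaled, where the call was lost as well. The call was also lost when any of 4 of the 6 arrays was left out. Those were control replicates 1 and 2 (adjusted p = 0.0949 and 0.223) and infected replicates 1 and 2 (adjusted p = 0.0595 and 0.217).

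**Figure D1:**
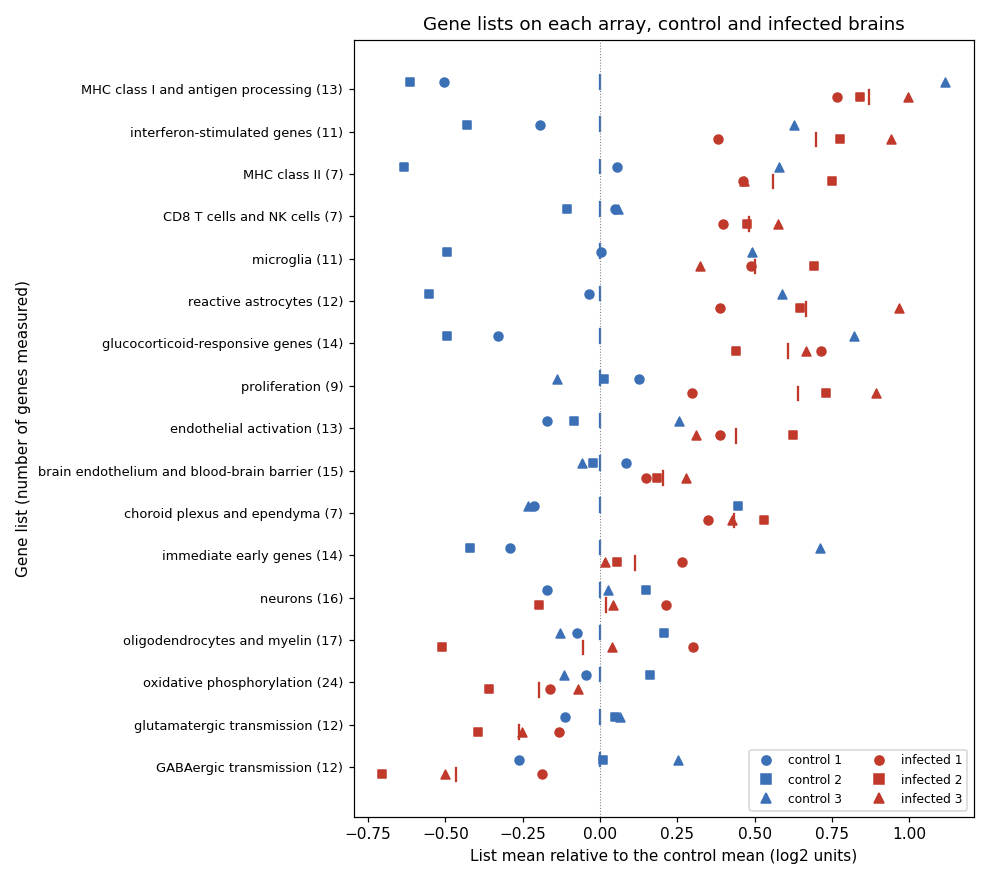
Mean of each gene list on each array, in log2 units relative to the control mean, with the list and its number of measured genes on the vertical axis; blue symbols are control brains, red symbols infected brains, symbol shapes replicates, and vertical bars group means. Control replicate 3 lies at 1.12 for MHC class I genes, beside the infected brains at 0.77 to 1.00, and at -0.14 for proliferation genes, below the infected brains at 0.30 to 0.89.

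Immune cell genes other than these did not pass here, and several lists passed under other settings. Genes of CD8 T cells and NK cells, the cytotoxic lymphocytes, were higher in 7 of 7 members with a median log2 change of 0.37 (camera, adjusted p = 0.0524). *Cxcr6*, a chemokine receptor of activated T cells, had a log2 change of 1.05 ± 0.35 (SE), with 2 values in each group. The estimated correlation and fry could not be used on this list, since too few members were measured on all 6 arrays. Microglial genes were higher in 9 of 11 (camera, adjusted p = 0.0682), MHC class II genes in 6 of 7 (camera, adjusted p = 0.108) and genes of monocytes, macrophages and neutrophils in 5 of 8 (camera, adjusted p = 0.413). Of the settings that kept all arrays and the preset correlation, CD8 T and NK cells passed in 8 of 16, microglia in 8 of 17, MHC class II in 5 of 16 and monocytes in 3 of 16. Without control replicate 3 the camera adjusted p was 4.36e-05 for microglia, with a median log2 change of 0.79, and 0.00073 for MHC class II. Microglia also passed without infected replicate 3 (camera, adjusted p = 0.0311), and CD8 T and NK cells without control replicate 2 (camera, adjusted p = 0.0392). *Aif1*, a calcium-binding protein of microglia and macrophages, had a log2 change of 0.72 ± 0.31 (SE), *Lyz2*, the lysozyme of myeloid cells, 1.06 ± 0.39 (SE), and *Ctss*, a protease that prepares class II molecules, 1.32 ± 0.51 (SE). The *Ctss* ratio in control replicate 3 was 2.05, above the infected mean of 1.97. *H2-Eb1*, the class II gene that was lower, had a log2 change of -0.57 ± 0.31 (SE). Cytokine and NF-kB target genes were higher in 7 of 9 (camera, adjusted p = 0.217), and passed without control replicate 3 (camera, adjusted p = 0.0215). In this list *Irf8*, a transcription factor of myeloid cells, had 1.07 ± 0.30 (SE). Chemokines had 4 measured members and B cells had 3, too few for a test. Among the chemokines *Cxcl12* had 1.01 ± 0.31 (SE), *Ccl5* 1.11 ± 0.53 (SE), *Ccl8* 0.27 ± 0.23 (SE) and *Cx3cl1* 0.01 ± 0.25 (SE). *Ccl5* had no value in control replicate 2. Its difference rested on control replicate 1, since control replicate 3 had -0.21 against an infected mean of -0.12. Among the B cell genes *Cd79b* had 1.13 ± 0.35 (SE) and *Ighm* 1.29 ± 0.46 (SE).

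Markers of the main brain cell types did not pass. Neuronal genes had a median log2 change of 0.03 with 9 of 16 higher (camera, adjusted p = 0.743), and their direction relative to other genes, the sign of the camera statistic, turned in 7 of the 23 other settings. Astrocyte genes were higher in 8 of 14 (camera, adjusted p = 0.846) and turned in 7, and genes of oligodendrocytes and myelin were lower in 9 of 17 (camera, adjusted p = 0.678) and turned in 3. Genes of glutamatergic transmission, the excitatory signalling of the brain, were lower in 8 of 12 with a median log2 change of -0.41 (camera, adjusted p = 0.146). *Grm3*, a metabotropic glutamate receptor, had -1.43 ± 0.37 (SE) and *Shank3*, a postsynaptic scaffold, -0.82 ± 0.27 (SE). The list passed in 3 of the 17 settings that kept all arrays and the preset correlation, among them the values as deposited (adjusted p = 0.00598). Voltage-gated ion channels had a median of 0.02 and a mean of -0.06, which differ in sign (camera, adjusted p = 0.701).

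**Figure D2:**
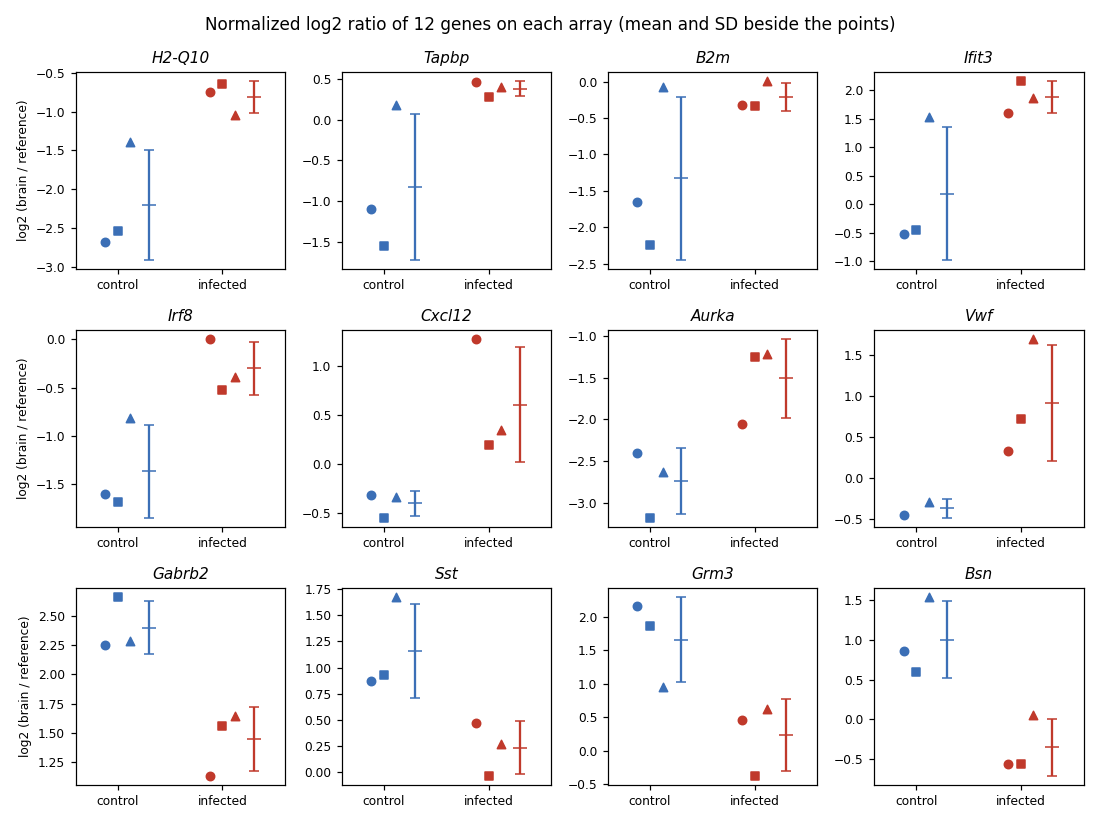
Normalized log2 ratio of brain over reference for 12 genes, 1 panel each with its own vertical scale, in control (blue) and infected (red) brains; points are arrays, symbol shapes replicates, and bars beside them the mean and SD. *B2m* spans -2.25 to -0.08 in control brains and *Gabrb2* lies at 2.25 to 2.66 in control against 1.14 to 1.64 in infected brains.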

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

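All tests of explanations in this part were chosen after the results they bear on had been seen. Of the spots outside the comparison because they lacked values in a group, 507 had a value on all 3 infected arrays and on no control array, and 128 had the reverse. Of the 507, 21 were spots of genes on a list. They include *Mx2*, *Oasl1*, *Ddx58* and *Ifi35* of the interferon list, the GTPase *Gbp9*, the chemokine *Ccl4* and the granule protease *Gzma*, but also the neuronal *Syt1* and *Camk2b*, the smooth muscle gene *Myh11*, the hormones *Gh* and *Hamp*, and 2 spots of the alpha globin *Hba-a1*. Of the 128, 3 were on a list: *Tyms*, of the proliferation list that rose, *Hmox2* and *Vcan*. These genes were named after their values were seen. The real split gave 507, the highest of the other 9 of 10 splits gave 322, and 1 of 10 splits gave as many; 10 splits are too few for a share under 0.05. Poor detection in 1 part of the control slides may account for much of this: 49.1% of the 507 spots lay in the fourth column of blocks, which holds 25% of all spots. Empty spots there made up 37.6% to 50.8% on control arrays and 27.8% to 30.8% on infected arrays. In the other columns they made up 31.4% to 43.8% on control and 32.1% to 43.7% on infected arrays. The fourth column was thus emptier than the others on each control array and fuller on each infected array, so the pattern was not one of the control slides alone. Whether the interferon spots exceed that pattern stays open. Of 7 interferon-list spots without a control value 4 were present on all 3 infected arrays, where their columns give 0.812, but the adjusted p over 17 lists was 0.0699 in an exact test stratified by column.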

How the results depend on the processing

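In limma, 0 features passed an adjusted p under 0.05 in each of the 23 other settings. Under 0.10, 0 passed here, and 2 passed with block medians unscaled, 25 without control replicate 3, 5 without infected replicate 3 and 0 in the other settings. An unadjusted p under 0.05 with a fold of at least 1.5 gave 1756, 986 higher and 770 lower, a looser rule. The 81 named genes kept their direction in 1730 of 1738 values, and 0 passed, the lowest adjusted p being 0.0563. The 8 that turned were all of *Gbp5*, near 0 here. Its log2 change was 0.2263 in the values as deposited, 0.1971 after median centring, 0.03195 after quantile normalization, 0.02509 with array weights and 0.04412 without dim spots. Leaving out 1 array it ran from -0.106 (infected replicate 1) to 0.04803 (control replicate 3). Adjusted p-values of lists are those of camera unless named. For lists, the cause of the changes was not tested unless stated. With an estimated correlation 0 lists rose and 0 fell, at an adjusted p of 0.607 for all 8 lists. The directional test of fry also gave 0 and 0, at 0.568 for glucocorticoid genes and 0.421 for the other 7. The fry test does not compare a list with other genes. Its test for changes of mixed direction passed antioxidant defence (fry, adjusted p = 0.0320).

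Against 6 lists that rose and 2 that fell, 11 rose in the values as deposited, 12 rose and 4 fell after median centring, 11 rose after quantile normalization, 14 rose with block medians unscaled, 10 rose with 1 spot per gene, and 3 rose and 1 fell without the 25% of features with the lowest ratios, which tests fewer genes. After print-tip loess, over genes on all 6 arrays and without dim spots 1 fell. Oxidative phosphorylation lost its call in the values as deposited (0.0752), after median centring (0.0587), block medians unscaled (0.373), print-tip loess (0.560), genes on all 6 arrays (0.100), without dim spots (0.0580) and without the lowest ratios (0.900). Endothelial activation lost it over genes on all 6 arrays (0.288), without dim spots (0.0580) and without the lowest ratios (0.0781), and reactive astrocytes without the lowest ratios (0.102). Neuronal genes turned lower after median centring, at 0.0499. MHC class I, interferon, glucocorticoid, proliferation and GABAergic lists kept direction and call in all 17 settings that left out no array and kept the preset correlation, at an adjusted p of at most 0.0340, except that proliferation was tested in 16: without the lowest ratios 2 of its 9 genes were left, too few for a test. Lists not called here were called in some: CD8 T and NK cells in 8 of 16, microglia in 8 of 17, choroid plexus in 6 of 16, MHC class II in 5 of 16, monocytes in 3 of 16, glutamatergic transmission, brain endothelium and junctions in 3 of 17, ion channels in 2 of 17, and apoptosis, haem and neurons in 1 of 17. The lowest for MHC class II was 0.000335, in the values as deposited.

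Leaving out 1 array at a time, lists that rose numbered 3 (without control replicate 1) to 13 (without control replicate 3) and lists that fell 0 (without infected replicate 2) to 2. The camera adjusted p ranged from 1.051e-16 to 0.0181 for MHC class I, 0.000886 to 0.0310 for proliferation and 1.874e-07 to 0.0872 for interferon genes. It ranged from 4.362e-08 to 0.123 for reactive astrocytes, 3.213e-09 to 0.113 for glucocorticoid genes and 0.0110 to 0.180 for endothelial activation. For GABAergic transmission it was 0.00185 to 0.119 and for oxidative phosphorylation 0.0139 to 0.223. These values take the preset correlation of 0.01. Over all arrays the estimated correlation was 0.855 for MHC class I, 0.627 for interferon, 0.397 for astrocyte and 0.691 for glucocorticoid genes. The lowest values of these lists, each without control replicate 3, therefore overstate the evidence.

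The replicate numbers do not pair the samples: same-numbered deviations correlated at 0.07, -0.02 and -0.02. With the replicate block 0 features passed, 8 lists rose and 1 fell, oxidative phosphorylation being at 0.0565. Signal over background was not analysed here, so dim spots limit the values by an unknown amount.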

Other observations

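All tests of explanations in this part were chosen after the results were seen, apart from the count of features past the threshold in other splits. Several lists outside those described above had members with large values, none past the threshold. In the erythroid list *Bpgm*, which makes the regulator of oxygen release by haemoglobin, had a log2 change of 1.16 ± 0.27 (SE) and *Hba-a1*, an alpha globin, had -1.23 ± 0.39 (SE), with 4 of 6 members higher (camera, adjusted p = 0.573). The *Hba-a1* value came from 1 spot with 2 values in each group, and 2 other spots of this gene had values on all 3 infected arrays and no control array. Genes of the choroid plexus and ependyma were higher in 6 of 7 (camera, adjusted p = 0.0748), with *Foxj1*, a factor of ciliated cells, at 1.10 ± 0.36 (SE). This list passed without control replicate 2 (camera, adjusted p = 0.0130). Genes of adherens and gap junctions were higher in 10 of 13 (camera, adjusted p = 0.0748), with *Cdh1*, E-cadherin, at 1.15 ± 0.29 (SE), and apoptosis genes in 8 of 9 (camera, adjusted p = 0.0988). The clock repressors *Bhlhe40* and *Bhlhe41* had 1.00 ± 0.32 (SE) and 1.05 ± 0.30 (SE), while the circadian list did not pass (camera, adjusted p = 0.306).

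In the stress lists, *Herpud1* and *Atf4* of the unfolded protein response had log2 changes of 0.79 ± 0.25 (SE) and 0.55 ± 0.23 (SE), and *Hspe1*, a mitochondrial chaperonin, had -0.63 ± 0.23 (SE), with 12 of 18 members of the heat shock list higher (camera, adjusted p = 0.413). *Bnip3*, a mitochondrial protein induced by hypoxia, had 0.76 ± 0.27 (SE), with 12 of 17 of the hypoxia and glycolysis list higher (camera, adjusted p = 0.306). Ribosomal protein genes were lower in 17 of 27 (camera, adjusted p = 0.180), with *Rplp1* at -0.79 ± 0.28 (SE) and *Rps2* at -0.57 ± 0.25 (SE). The adjusted p from camera was 0.138 for haem and iron genes, 0.445 for neurotrophins, 0.672 for both pericytes and antioxidant defence, 0.701 for complement and 0.837 for immediate early genes. Without control replicate 3 it was 0.00167 for haem and iron, 0.00617 for immediate early, 0.0372 for complement and 0.0417 for hypoxia and glycolysis genes. The median log2 change was then 0.62 for immediate early genes, against 0.17 here, and 0.87 for complement, against 0.26. Ribosomal protein genes passed without control replicate 2 (camera, adjusted p = 0.0392). Precursors of oligodendrocytes had 3 measured genes, the pituitary 3 and platelets 2, with medians of 0.05, -0.17 and -0.14.

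The real split of the 6 arrays gave 0 features past the adjusted threshold in limma, and so did 10 of 10 splits, with 0 the highest of the others. At an unadjusted p under 0.05 the real split gave 1854 features and the highest other 1268, and 1 of 10 splits gave as many. For lists called at the preset correlation, the real split gave 8 and the highest other 14, and 4 of 10 splits gave as many. The split with 14 set control replicates 1 and 2 and infected replicate 1 against the rest. With 10 splits a share under 0.05 cannot be had. With an estimated correlation and with the directional test of fry, 0 lists were called in the real split.

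Control replicate 3 lay at the infected level of MHC class I genes, at 1.12 in the list mean. An exchange of labels with an infected sample is argued against by the lowest infected list mean of 0.767, above control replicates 1 and 2 at -0.50 and -0.61. An array-wide trend with the log ratio is argued against because its difference from the other controls lay at percentile 100 among 10000 lists matched on that ratio. A brain like the other infected ones with a wrong label stays open. Of 21 tested lists in which the infected brains lay on 1 side of control replicates 1 and 2, this control reached or passed the infected range in 14, among them MHC class I and II, interferon, microglia, reactive astrocytes, glucocorticoid genes and complement. Passing the range counted as reaching it. This control lay at 0.71 for immediate early genes, against 0.01 to 0.26 in the infected brains. It lay at 0.60 for complement against 0.11 to 0.34, and at 0.40 for haem and iron genes against 0.29 to 0.36. For MHC class I and glucocorticoid genes it also lay above the infected range, so the 14 do not all show likeness to the infected brains. It fell short by more than the infected SD in 5, those of CD8 T and NK cells, proliferation, brain endothelium, junctions and glutamatergic transmission, and by less in 2. No biological explanation was tested for this animal, since the labels give none within the control group.

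Among the 10 named genes with the smallest p on the higher side are *Cyp2c40*, *Mep1a* and *Myl7*, better known from other organs. RNA of other tissues in the infected samples stays open. Of 20 measured genes of liver, kidney, heart, lung, stomach, spleen or gonad, 15 were lower and 5 higher. At an unadjusted p under 0.05 in limma 7 were lower and 3 higher. Their median log2 change was -0.77, with a 95% bootstrap interval over genes of -0.90 to -0.47, which takes the genes as independent. The lower ones include the sperm genes *Prm1* (-1.45), *Prm2* (-0.89), *Tnp2* (-0.63) and *Tnp1* (-0.46). The mice were female, so RNA of these genes could not have come from their other tissues. What lowered them was not tested, and counts and a median that include them do not argue against such RNA. Per array, however, the list means differed by -0.50, infected less control, with groups that overlapped (exact permutation p = 0.3). Whether the fall of this list depended on the processing was not settled. For the values as deposited only the median over the list's measured spots was taken, and the spots, 25 to 31, differed between arrays. It is therefore another measure than the change per gene. This median was -3.84, -4.39 and -3.87 in control replicates 1 to 3. It was -3.57, -3.44 and -5.89 in infected replicates 1 to 3, so only infected replicate 3 lay below the controls. The heart genes among them went both ways, and no list of gut genes was fixed. Noise of a dim brain channel may contribute: the median percentile of their mean brain intensity was 20.5 among all features, against 67.3 for the 10 genes on the lower side. Among the 25% of features with the lowest log2 ratios 17.2% had an unadjusted p under 0.05 in limma, and among the others 9.27%. That split is on the ratio and not on brain intensity, so it cannot decide whether noise of a dim channel contributed. Infection as the cause of these differences stays open and untested.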
